A study of Mus musculus with 15 samples.

How the data were processed

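The series measured total RNA of mouse whole hearts on Affymetrix mouse expression arrays with 45101 probe sets. Per the labels, hearts were frozen in liquid nitrogen, RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. The labels give 1 control and 1 aldosterone array at each of 7 times (0.5, 1, 2, 3, 4, 5 and 12 h) and 1 control array at 0 h without an injection, 15 arrays in all. The labels do not say whether an array stands for 1 animal or a pool, so p-values measure only the spread between arrays, which may be technical. The labels give neither the dose nor what the timed controls received.

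The deposited values are linear signals per probe set, made with GCOS 1.2 per the submitters' processing notes. The deposited signals had a 2% trimmed mean of 1500 on each array, and their medians ran from 413.8 to 741.4. The number of arrays limits the precision. No genome was used, and gene symbols came from the platform annotation, with 1 symbol for 34958 probe sets, several for 932 and none for 9211. Of 40 gene lists holding 695 pairs of list and gene, 635 pairs matched a symbol, and 35 lists had at least 5 tested genes.

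The designs, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Signals were put on a log2 scale after adding 167.8, the 25th percentile of all signals, so folds of low genes are understated. Quantile normalization followed because array medians differed by 1.79-fold, above the limit of 1.3 set for leaving the deposited scaling alone. One of the planning lists had named the deposited scaling as the main choice, and it was run as the alternative. The 21272 probe sets with a mean at or above the median signal of 526.7 were tested, covering 11228 genes.

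Tests used limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading and matplotlib 3.10.9 for figures. Moderated tests used a variance trend on the mean, and calls had a Benjamini-Hochberg adjusted p under 0.05. The aldosterone effect was fitted with time as a 7-level block, over all times, in windows of 0.5 to 2 h and 3 to 5 h, as the difference of those windows, and as a smooth course (a moderated F over treatment and its linear and quadratic terms in time order). The time effect (moderated F), 12 h against 0.5 to 5 h, and the trend over the 12 arrays from 0.5 to 5 h were fitted with treatment as a covariate. The 12 h and trend fits counted both arrays of a time as separate, though these shared their time and scan day. Their SE and p values may therefore be too small. Single pairs and the uninjected array were given as values without a test. Gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, on 1 probe set per gene (the one with the highest mean signal). The targets of the corticosteroid receptors had an exact sign-flip test over the 7 differences between arms, with 128 flips and a smallest two-sided p of 0.0156. For the uninjected array, list medians were set against 10000 random lists matched on mean expression.

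Named genes were taken by rule: the 10 with the smallest unadjusted p for the aldosterone effect, since none was called; the 5 with the smallest unadjusted p per window; up to 10 per direction for the trend and 12 h; and up to 4 members per list by the size of their statistic. The corticosteroid targets could be named anywhere. Symbols with several probe sets take the called one or the one with the highest mean.

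The steps were tested on simulated data with changed genes inserted at known folds. For the aldosterone effect over 7 times, 46.3% of 1.5-fold, 89.6% of 2-fold and 100% of 3-fold changes were recovered among 21272 probe sets. At 3 to 5 h, 13.4% of 1.5-fold and 59.7% of 2-fold changes were recovered, and at 0.5 to 2 h 14.9% and 46.3%. For the trend, 7.46% of simulated 1.5-fold and 43.3% of 2-fold changes were recovered, and for 12 h 14.9% and 53.7%. Each change had the same size at all times of its comparison, or followed a straight line for the trend, with noise independent between arrays. These rates may therefore overstate the recovery of brief changes, and of changes in the trend and 12 h fits, where arrays of a time shared their scan day. A 1.5-fold shift of the 34 measured corticosteroid targets was called in 20 of 20 simulated draws. Noise in these draws was independent between genes, while the estimated correlation of this list in the data was 0.11. The draws may therefore overstate how often a real shift of the list would be called.

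The arrays' experiment files gave 3 scan days and 2 chip lots. Day 1 (lot 1) held the 0.5 and 3 h pairs, day 2 the 1, 4 and 12 h pairs, and day 3 the 2 and 5 h pairs and the uninjected array. Both arms of a time shared their day, so the time block already absorbs day and lot in the aldosterone tests. The files also gave a station, which differed between the arms only at 5 h (2 in control, 1 in aldosterone). The time block does not absorb it, and its effect was not tested. Alternatives covered scaling, offset, filter, variance model, array weights, each time left out, scan day and lot. The Gapdh 3′/5′ signal ratio as a covariate, list tests of the windows and the trend, and enrichment of lists among genes called for time were added after seeing the data.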

Results

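Whole-heart expression was measured on 15 arrays to follow the response of the mouse heart to aldosterone, the adrenal mineralocorticoid, over time. Each arm, control and aldosterone, had 1 array at 0.5, 1, 2, 3, 4, 5 and 12 h, and 1 further control array at 0 h was labelled as without an injection. The 7 times stand in for replicates in the comparison of the arms, and each time had 2 arrays in the comparison of times. Array medians ran from 413.8 to 741.4 in deposited signal units.

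The first question was whether genes regulated by the corticosteroid receptors differed between the arms. By limma none of the 34 measured targets passed, over all genes or adjusted over the list alone (smallest 0.424). The highest means were those of Map3k6, a stress kinase gene, and Fkbp5, which encodes a co-chaperone of the steroid receptors. Map3k6 differed by 0.29 on the log2 scale (SD of differences 0.17, n = 7 times, higher in 6 of 7; exact sign-flip p = 0.0312) and Fkbp5 by 0.28 (SD 0.36, higher in 6 of 7; exact p = 0.0312), or by 0.15 without the 12 h pair. The smallest exact p adjusted over the list alone was 0.531. With 7 times the exact test has a smallest p of 0.0156 and could not have called 1 gene among 34 on its own. It could have called genes only if many of them together had p values at or near that smallest p. Sgk1, the kinase that raises sodium channel activity in the kidney, had a mean difference of -0.03 (SD 0.25, n = 7). Tsc22d3, the glucocorticoid-induced leucine zipper, had 0.16 (SD 0.28), and the clock gene Per1 had -0.12 (SD 0.60). Zbtb16, a zinc finger repressor induced by glucocorticoids, had -0.27 (SD 0.42, higher in 2 of 7), and its other probe sets had 0.26 and -0.98. A second probe set of Fkbp5 had -0.01. On 1 probe set per gene, the 95% limma intervals of the mean over 7 times excluded a 2-fold change in either direction for all 34 genes, and 1.5-fold for 33. They do not cover single times or other probe sets, such as that of Zbtb16 at -0.98. The receptors themselves had mean differences of 0.09 (Nr3c1, the glucocorticoid receptor, SD 0.44) and 0.14 (Nr3c2, the mineralocorticoid receptor, SD 0.36).

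**Figure D1:**
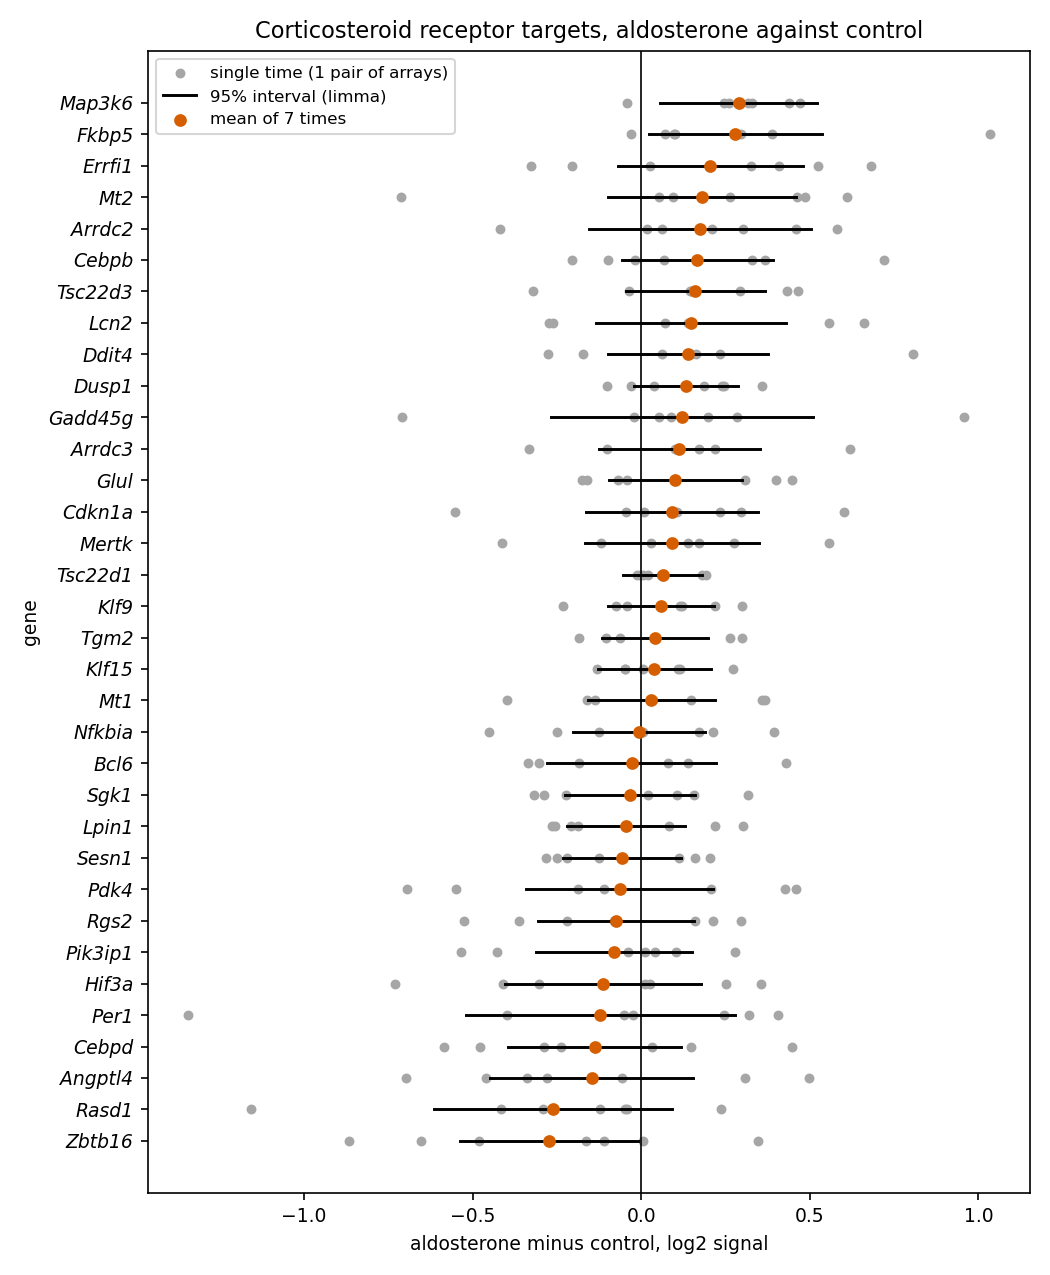
Differences between aldosterone and control (log2 signal, x axis) for the 34 measured corticosteroid receptor targets (y axis). Grey points are the 7 times, orange points their mean and black lines the limma 95% interval; all means lie between -0.27 and 0.29.

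Over all 7 times, no probe set was called by limma, against 934 at an unadjusted p under 0.05 (4.39% of 21272). The genes with the smallest unadjusted p, none of them called, included Dnaja1, an Hsp40 co-chaperone gene, with a difference of 0.43 ± 0.09 (SE, n = 7 pairs, higher in 7 of 7; other probe sets 0.06 and 0.09). Lcp1, the leukocyte actin-bundling protein L-plastin, had 0.51 ± 0.11 (7 of 7), with another probe set at -0.09. Myl1, a skeletal muscle myosin light chain, had 0.38 ± 0.08 (7 of 7), and Ift57, an intraflagellar transport gene, 0.56 ± 0.13 (7 of 7). Zc2hc1a had 0.48 ± 0.11 (7 of 7), with another probe set at -0.01. Tuba3b, a testis-type alpha tubulin, had -1.06 ± 0.24 (higher in 0 of 7), the syndecan gene Sdc3 -0.79 ± 0.17, and Pigu, of the GPI transamidase, -0.60 ± 0.12. Lta4h, the leukotriene B4 synthase, had -0.67 ± 0.16 with another probe set at 0.07, and Wdr33, of the mRNA cleavage machinery, had -0.40 ± 0.10 with 2 of its 4 other probe sets in the opposite direction. For 97.9% of probe sets the 95% interval lay within a 2-fold change, and the median SE was 0.14.

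Macrophage markers were the 1 list of 35 called over the 7 times. They were higher with aldosterone by a median of 0.18 (11 of 13 genes higher; camera adjusted p = 0.00422). The call was lost with an estimated correlation (adjusted p = 0.999 with an estimated correlation), and no member passed the test over all genes or adjusted over the list alone. Adgre1, the gene of the F4/80 antigen, had 0.30 ± 0.10 (higher in 7 of 7), the lysozymes Lyz2 and Lyz1 0.31 ± 0.12 and 0.31 ± 0.12 (6 of 7 each), and the complement gene C1qc 0.28 ± 0.11 (6 of 7). Without the 3 h pair the list had an adjusted p of 0.136 and without the 4 h pair 0.216.

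No single gene was called by limma in either window, for the difference between the windows or for a smooth time course. At unadjusted p under 0.05 there were 2226 probe sets at 0.5 to 2 h, 684 at 3 to 5 h, 1436 for the difference and 1189 for the smooth course. At 0.5 to 2 h the smallest p values belonged to Hdlbp (an RNA-binding protein, -2.15 ± 0.32), the macrophage gene Retnla (1.07 ± 0.18), the globin gene Hbb-b2 (-0.86 ± 0.15), Rusc2 (-0.80 ± 0.14) and the splicing gene Snrnp27 (0.59 ± 0.11). At 3 to 5 h they belonged to Yif1a (-1.09 ± 0.14), Scand1 (1.05 ± 0.18), Tuba3b (-1.64 ± 0.32), Agfg2 (1.53 ± 0.32) and Sp110, an interferon-inducible nuclear body gene (-0.97 ± 0.21). For the later minus the earlier window they belonged to Yif1a (-1.65 ± 0.20), Hdlbp (2.96 ± 0.45), Scand1 (1.66 ± 0.25), the perlecan gene Hspg2 (2.03 ± 0.31) and the inducible chaperone gene Hspa1b (higher in the later window). The opposite direction was seen in 1 of 2 other probe sets of Hdlbp and in the 1 other probe set of Hbb-b2 and of Hspg2. For Yif1a it was seen in 1 of 2 at 3 to 5 h and in 2 of 2 for the difference. The Gapdh 3′/5′ ratio was higher in aldosterone by 2.54 (log2) at 1 h and 3.00 at 2 h, and without the 0.5 h pair 235 probe sets were called at 1 and 2 h (17 higher, 218 lower), of which 0 stayed with that ratio as a covariate. Without the 0.5 h pair 31 were called for the difference of the windows, and without the 2 h pair 1 was called for the smooth course, sarcolipin (Sln, adjusted p = 0.00188), an atrial marker, and atrial transcripts differed between arrays.

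In the single 12 h pair, which has no replicate check, 657 probe sets were over 2-fold higher and 638 over 2-fold lower with aldosterone (6.09%). The other pairs had between 563 and 1289 such probe sets. Fkbp5 was 1.03 (log2) higher with aldosterone at 12 h.

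More genes were called for time, over both arms together, than between the arms. The spread in this test came only from the 2 arrays of a time, which shared their scan day. The test therefore cannot part time from anything else that both arrays of a time shared, and its p values may be too small for time itself. The lung transcripts of both 1 h arrays, described below, were called for time in this way. limma called 413 probe sets of 321 genes for time (4070 at unadjusted p under 0.05). Lists were counted on 1 probe set per gene, the one with the highest mean signal, where 189 of 11228 genes were called (1.68%). On that count corticosteroid targets were the list with the most called genes, 14 of 34 (Fisher's exact test, adjusted p = 3.3e-15; 27 of 34 adjusted over the list alone). Mt2, a zinc-binding metallothionein, had its lowest mean at 0.5 h (12.24) and its highest at 4 h (15.87), a 12.3-fold range (SD of the arm differences 0.44, n = 7; adjusted p = 0.000249). Zbtb16 had a 4.64-fold range with its highest mean at 3 h (SD 0.42; adjusted p = 0.00240), Map3k6 2.99-fold (SD 0.17; adjusted p = 0.0126) and Klf15, a glucocorticoid-induced metabolic regulator, 2.48-fold (SD 0.14; adjusted p = 0.0139). Fkbp5 had a 2.22-fold range and did not pass (adjusted p = 0.0628). Within scan days 13 of the 34 targets were called, and without the 0.5 h pair 5 were. The share called was higher in the lung (6 of 6), acute phase (6 of 11) and cytokine (7 of 16) lists. Fisher's test treats genes as independent, which genes measured on the same arrays are not, so its p values here and below may be too small.

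Cytokine, acute phase and immediate early genes also differed between the arrays of different times, with different times of their highest means. The lists overlap with the corticosteroid targets: 4 of the 6 called acute phase genes (Mt2, Mt1, Cebpd and Lcn2), Nfkbia among the cytokine genes and Dusp1 among the immediate early genes are counted in both, as is Lcn2 among the neutrophil genes. Among cytokines, chemokines and NF-kB targets 7 of 16 were called (12 of 16 adjusted over the list alone; Fisher adjusted p = 4.0e-08; 5 within scan days and 5 without the 0.5 h pair). Icam1 and Vcam1, endothelial adhesion molecules for leukocytes, were 18.0-fold and 9.37-fold higher at 2 h than at 0.5 h (SD of the arm differences 0.67 and 0.43; adjusted p = 0.00240 and 0.00108). Socs3, a feedback inhibitor of cytokine signalling, was 16.3-fold higher (SD 0.49; adjusted p = 0.00108), and Nfkbia, the NF-kB inhibitor, 2.54-fold higher (SD 0.29; adjusted p = 0.00310). Acute phase and metallothionein genes had 6 of 11 called (11 of 11 adjusted over the list alone; Fisher adjusted p = 7.9e-08; 6 within scan days and 4 without the 0.5 h pair). Cebpd, a transcription factor of the acute phase, was highest at 2 h, 5.48-fold over 0.5 h (SD 0.37; adjusted p = 0.000883), and the siderophore binder Lcn2 at 12 h, 8.42-fold over 0.5 h (SD 0.36; adjusted p = 0.000964). Of 24 immediate early genes 7 were called (15 adjusted over the list alone; Fisher adjusted p = 6.5e-07), among them Zfp36 and Egr1, both highest at 2 h, and Klf2, highest at 0.5 h; within scan days 4 were called and without the 0.5 h pair 1.

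Neutrophil markers had 3 of 8 called (6 adjusted over the list alone; Fisher adjusted p = 0.00108), and the calprotectin genes S100a8 and S100a9 were highest at 1 h, 4.00-fold and 6.17-fold over 0.5 h (SD 0.66 and 0.79). Both 1 h arrays also carried lung transcripts: all 6 tested lung epithelium markers were called, and without the 1 h pair 0 of them and 1 of the neutrophil markers were. Enrichment passed in 4 further lists: the vascular inflammation and fibrosis genes (5 of 17), the clock genes (4 of 18), and the white fat (2 of 7) and B cell markers (2 of 8). Within scan days 2, 3, 0 and 0 of these were called over all genes (8, 8, 4 and 2 adjusted over the list alone, against 12, 10, 4 and 4 without the block), and without the 0.5 h pair 2, 2, 1 and 0. Of the probe sets called for the time effect common to both arms, 113 had their highest mean at 0.5 h and 127 their lowest. The count of 413 was 87 without the 0.5 h pair, 899 without the 2 h pair, 183 without the 5 h pair and 255 without the 12 h pair. It was 108 with scan day as a block, 216 with the Gapdh ratio as a covariate and 54 without the variance trend. Mt2, Zbtb16, Map3k6, Icam1, Vcam1, Socs3, Cebpd and Lcn2 each kept an adjusted p under 0.05 without that trend (highest 0.0485), while Nfkbia (0.0663), S100a8 (0.0806), Klf15 (0.0902), S100a9 (0.104), Zfp36 (0.113), Egr1 (0.117) and Klf2 (0.142) did not.

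**Figure D2:**
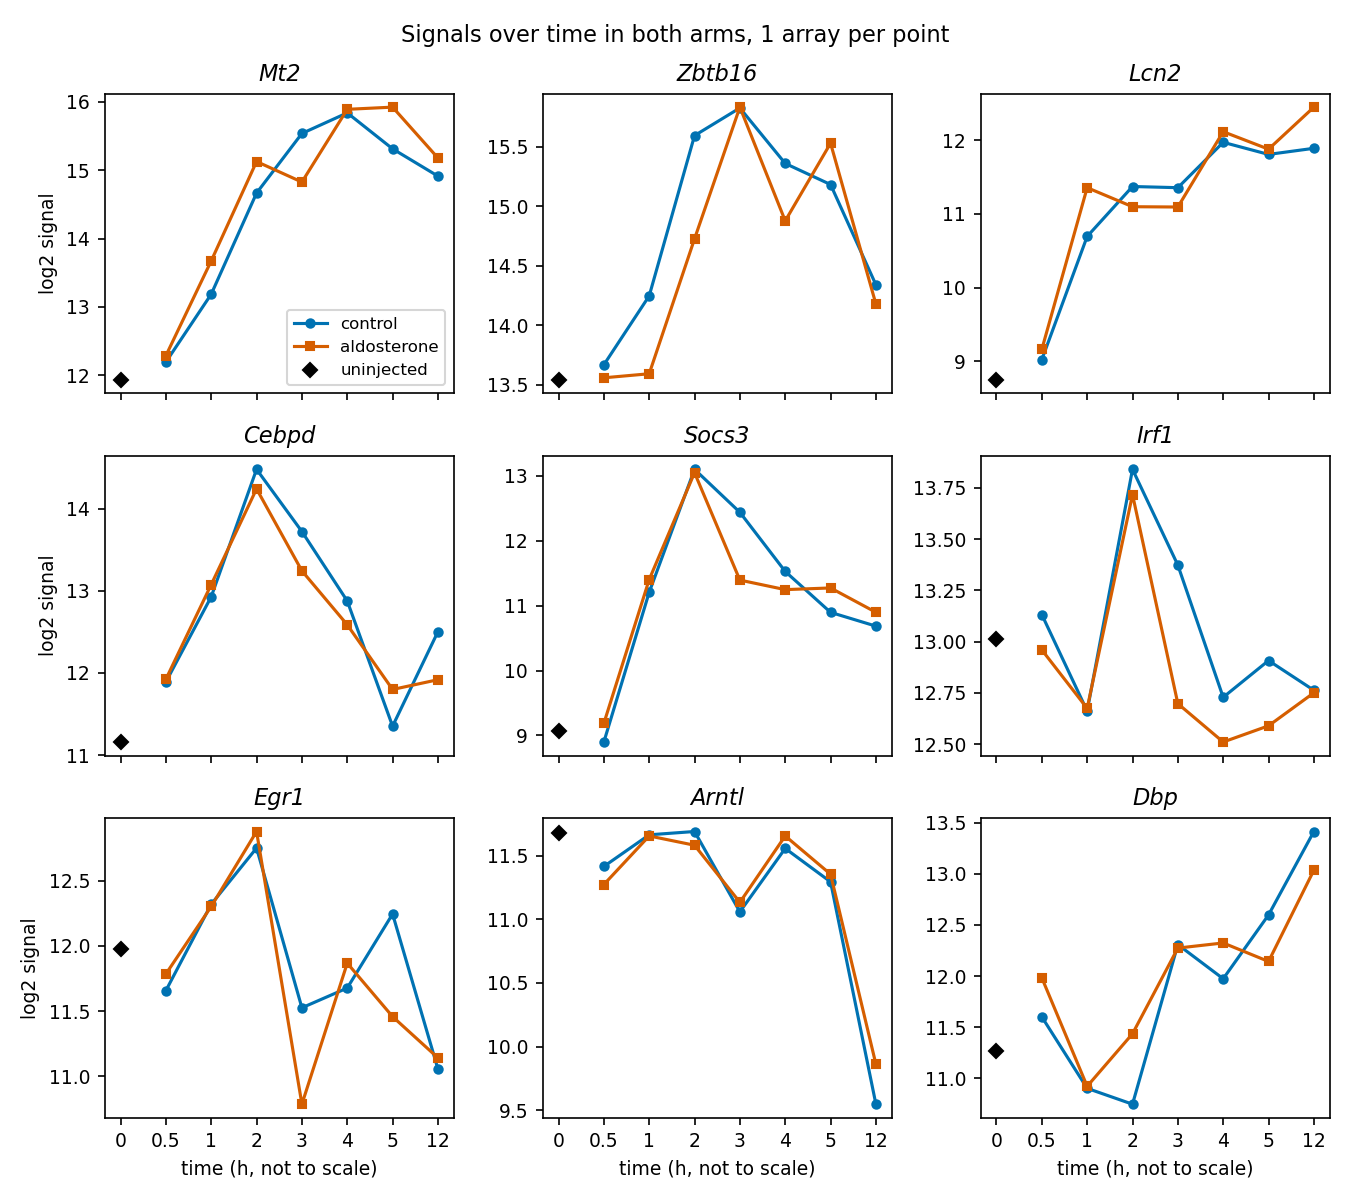
Log2 signals (y axis) of 9 genes over time in h (x axis, not to scale) in control (blue), aldosterone (orange) and uninjected (black) samples, 1 array per point. Socs3 is highest at 2 h, and Arntl is lowest and Dbp highest at 12 h.

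From 0.5 to 5 h, single genes such as the metallothionein Mt2 rose over both arms together. The acute phase and interferon response lists were called as rising too, but not with an estimated correlation (adjusted p = 0.149 and 0.0704). limma called 35 probe sets for a trend, 33 rising, of 24 genes and 8 unnamed probe sets (2008 at unadjusted p under 0.05). The trend fit counted both arrays of a time as separate, so its SE and p values may be too small. Mt2 rose by 0.73 ± 0.10 log2 units per h (SE; adjusted p = 0.0134) and the protease inhibitor gene Serpina3n by 0.67 ± 0.11 (adjusted p = 0.0240). Zbtb16 rose by 0.64 ± 0.09 on 1 probe set (adjusted p = 0.0102), while its probe set with the highest signal had 0.39 ± 0.09 and did not pass (adjusted p = 0.142). Among the others named were the interferon-induced GTPase Gbp2 at 0.52 ± 0.08 (adjusted p = 0.0193) and the serum amyloid gene Saa3 at 0.46 ± 0.06 (adjusted p = 0.0102). Slopes were 0.44 for Ms4a6d, 0.40 for Timeless, 0.39 for the Fc receptor gene Fcgr1, 0.37 for Fcgr2b and 0.37 for the interferon-induced ligase gene Herc6, and another probe set of Fcgr2b had -0.02. On the 12 arrays used to choose them, these 10 genes were higher in 6 of 6 comparisons of the later with the earlier array of an arm and scan day, which restates that choice. The slopes of the arms had a Pearson correlation of 0.34 across all probe sets, which are not independent. No probe set was called in limma for a difference of the slopes between the arms (648 at unadjusted p under 0.05), and 0 were called in either arm alone. Of 100 orders of the times, 6 gave as many calls as the real one.

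Among the lists, tested for this trend after seeing the data, interferon response genes rose by a median of 0.23 per h (16 of 18 with a positive slope; 3 called over all genes and 14 of 18 adjusted over the list alone; camera adjusted p = 1.1e-14; adjusted p = 0.0704 with an estimated correlation). Examples were Oasl2 at 0.31 ± 0.05, Ifit3 at 0.36 ± 0.06 and Irf7, the master regulator of type I interferon, at 0.22 ± 0.04. Acute phase and metallothionein genes rose by 0.21 per h (9 of 11; 4 called over all genes and 7 adjusted over the list alone; adjusted p = 6.3e-10; adjusted p = 0.149 with an estimated correlation). Immediate early genes fell (median -0.07 per h, 18 of 24 genes; 0 called over all genes and 4 adjusted over the list alone; adjusted p = 0.000359; adjusted p = 0.361 with an estimated correlation), with Klf2 at -0.18 ± 0.04 and Fos at -0.16 ± 0.04. Clock genes rose (median 0.06, 14 of 18; adjusted p = 0.00566) and smooth muscle and pericyte markers fell (median -0.05, 10 of 11; adjusted p = 0.00304), both with adjusted p = 0.0704 with an estimated correlation. Corticosteroid targets rose (median 0.06, 21 of 34; 2 called over all genes and 12 adjusted over the list alone; adjusted p = 0.0106; adjusted p = 0.558 with an estimated correlation), and this call was lost without the 0.5 h pair. In all 11 lists were called, 6 up and 5 down, and 0 with an estimated correlation. For the trend from 0.5 to 5 h the count of 35 was 3 without the 0.5 h pair, 2 without the 4 h pair, 16 without the 5 h pair and 21 without the 2 h pair; with scan day as a block it was 48, of which 27 were among the 35. It was 111 with the Gapdh ratio as a covariate, 17 without the variance trend, 55 with a stricter filter and 64 with array weights.

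At 12 h, single clock genes and the list of chaperone genes differed from the earlier times, and so did the immediate early genes, though not with an estimated correlation (adjusted p = 0.310). The 12 h fit counted both arrays of a time as separate, so its SE and p values may be too small. Arntl, the core clock activator BMAL1, fell by 1.74 ± 0.18 (log2, SE) at 12 h (adjusted p = 0.00108), with both arrays below all 12 earlier ones, and another probe set of it had 0.59 without passing. Npas2, its partner in the clock, fell by 1.54 ± 0.22 (adjusted p = 0.0202), also below all 12. Tef and Dbp, output factors of the clock, were 0.70 ± 0.15 and 1.46 ± 0.41 higher than before and above all 12 earlier arrays, but did not pass over all genes (adjusted p = 0.0974 and 0.301). Of the 18 clock genes 2 were called over all genes and 6 adjusted over the list alone (4 higher, 2 lower), and as a list they were not called (9 of 18 higher; camera adjusted p = 0.877). limma called 13 probe sets in all, 1 higher and 12 lower (1991 at unadjusted p under 0.05). The higher one was Mid1ip1, a regulator of fatty acid synthesis (0.85 ± 0.15). Lower ones besides the clock genes were Gga1 (-1.90 ± 0.33), Tmem82 (-1.71 ± 0.21), Epdr1 (-1.69 ± 0.26), Sh3pxd2b (-1.62 ± 0.25), Alkbh4 (-1.56 ± 0.25), Prss44 (-1.34 ± 0.20), Ints5 (-1.30 ± 0.22) and Tmem74b (-1.27 ± 0.21). Other probe sets of Epdr1 and Ints5 had 0.17 and 0.07.

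Heat shock and chaperone genes fell at 12 h (median -0.20; 15 of 18 lower, 6 of them called adjusted over the list alone and 0 over all genes; camera adjusted p = 3.3e-07; adjusted p = 0.00384 with an estimated correlation). Both arrays lay below all 12 earlier ones for Dnaja1 (-0.68 ± 0.12, on its probe set with the highest signal), the constitutive Hsp70 gene Hspa8 (-0.48 ± 0.09), the inducible Hspa1a (-1.31 ± 0.34) and the co-chaperone Bag3 (-0.51 ± 0.17). Immediate early genes also fell (median -0.47; 19 of 24 lower; adjusted p = 4.3e-07; adjusted p = 0.310 with an estimated correlation), with Fos at -1.12 ± 0.24 and Ier2 at -0.55 ± 0.18. Cytokine and NF-kB genes fell (median -0.52; adjusted p = 0.0353; adjusted p = 0.923 with an estimated correlation), for example Tnfaip3 at -1.54, and this call was lost without the 2 h pair (adjusted p = 0.142) or the 3 h pair (adjusted p = 0.0842) and with scan day as a block (0.0956). Atrial markers were called higher (median 1.02, 7 of 7; adjusted p = 0.0102; adjusted p = 0.923 with an estimated correlation), but not with scan day as a block (adjusted p = 0.311) or with the Gapdh ratio (0.316), which was 15.2 and 5.64 on the 12 h arrays. Their medians at 12 h (0.92 and 0.69 relative to the mean of the timed arrays) lay below the highest single earlier control (1.32 at 2 h). The count of 13 was 2 without the 1 h or the 5 h pair, 3 without the 3 h pair, 6 without the 2 h pair or with the Gapdh ratio as a covariate, and 20 without the 4 h pair. It was 1 with scan day as a block (Arntl) and 1 with a stricter filter, 2 with an offset at the median, 22 with a floor and 25 without a filter.

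The uninjected array had low signals of acute phase, cytokine and interferon genes beside the mean of the 6 control arrays from 0.5 to 5 h, without a test, and the 0.5 h control was about as low. Relative to the mean of the timed arrays, list medians in the uninjected and the 0.5 h control array were -1.42 and -1.06 for acute phase genes, -1.10 and -1.13 for cytokines, -0.66 and -0.52 for interferon genes and -0.53 and -0.45 for corticosteroid targets. The median difference from the 6 controls was -1.36 (log2) for acute phase and metallothionein genes (9 of 11 lower, 5 below all 6), -1.21 for cytokines, chemokines and NF-kB targets (15 of 16 lower, 4 below all 6), -0.70 for interferon response genes (18 of 18 lower, 8 below all 6) and -0.48 for corticosteroid targets (31 of 34 lower, 18 below all 6). Each of the 4 medians lay at percentile 0 of 10000 random lists of the same size, which leaves out the spread between arrays, and with the deposited scaling they were -1.05, -0.85, -0.53 and -0.65, where the median of all probe sets was 0.01. Mt2 was -2.52, Lcn2 -2.29 and Cebpd -1.72 relative to the controls, and Zbtb16 -1.44. The neutrophil markers S100a8 and S100a9 were -2.06 and -3.66, while the median of their list was -0.45 (5 of 8 lower) and -0.11 with the deposited scaling. The 6 controls include the 1 h array, where neutrophil markers had a median of 0.45 relative to the mean of the timed arrays. Atrial markers were higher than the 6 controls by a median of 1.77, but single controls varied widely, up to 1.32 (2 h) relative to the mean of the timed arrays, against 1.45 in the uninjected array. For the uninjected control at 0 h against control at 0.5 to 5 h, 1502 probe sets were over 2-fold apart (474 higher, 1028 lower; 609 and 539 with the deposited scaling), against 323 to 1123 for single control arrays set against the other 5. Quantile normalization moved the median of this array by 0.27, the largest shift among the arrays.

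Lung, atrial and white fat transcripts and RNA quality differed between arrays. White fat marker medians ran from -1.46 (aldosterone 5 h) to 2.01 (control 2 h), relative to the mean of the timed arrays. At 0.5 h the atrial gene Sln had deposited signals of 2094.4 in control and 15201 in aldosterone and the atrial light chain Myl7 6519.4 and 34184. Of the 10 listed lung genes 8 were above every other array in both 1 h arrays. The club cell gene Scgb1a1 had deposited signals of 120440 (control) and 252560 (aldosterone) at 1 h against at most 2745.7 elsewhere, and the surfactant gene Sftpc had 38710 and 106310 against at most 1029.4. The Gapdh 3′/5′ ratio ran from 0.887 to 15.2 among timed controls and from 0.853 to 10.2 with aldosterone. At 1 h it was 1.71 in control and 9.93 in aldosterone, and at 2 h 1.28 and 10.2.

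**Figure D3:**
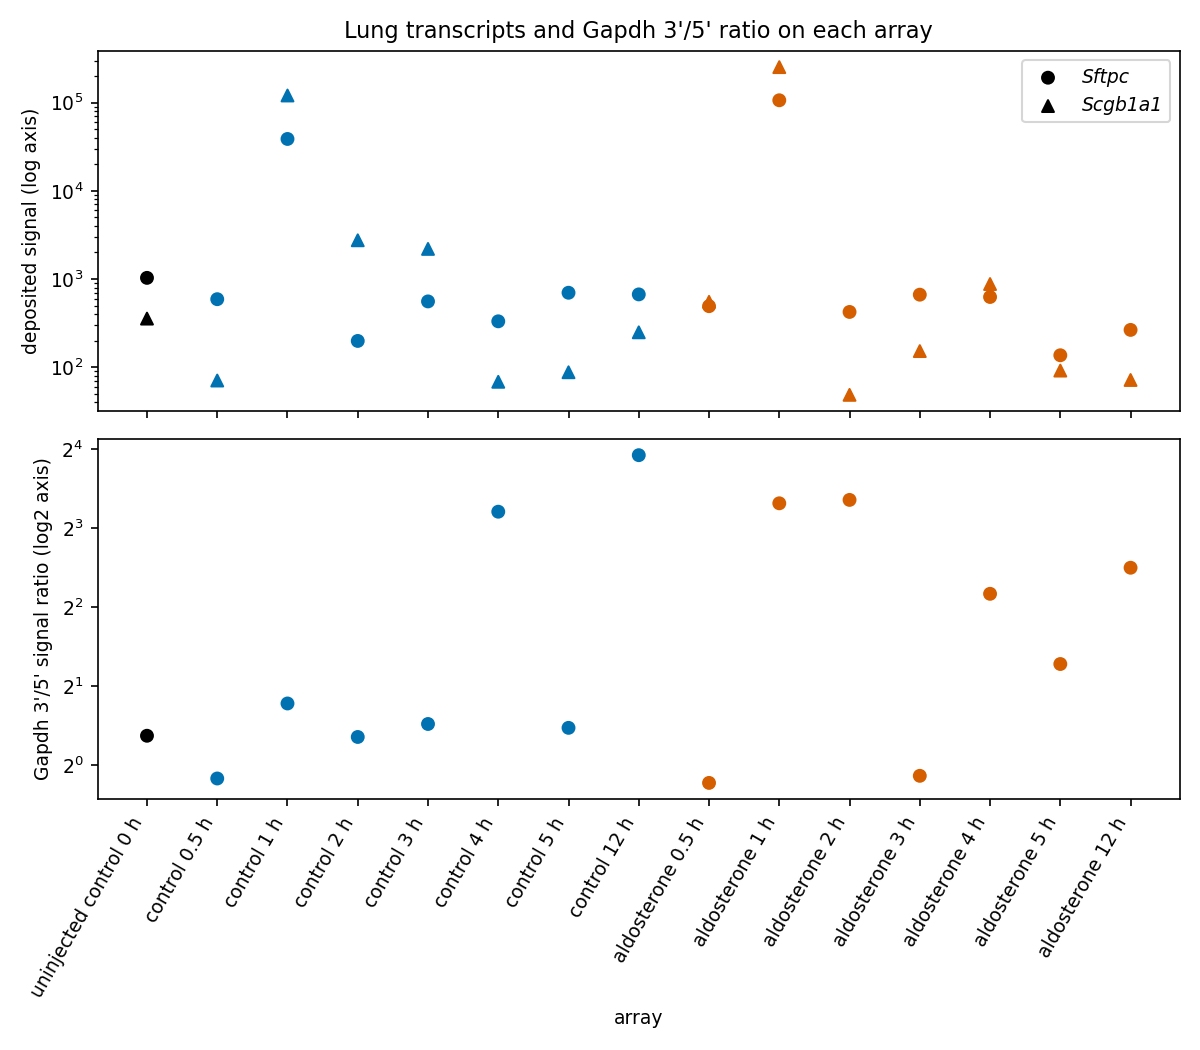
Deposited signals of the lung genes Sftpc and Scgb1a1 (upper panel, log axis) and the Gapdh 3′/5′ signal ratio (lower panel, log2 axis) on each of the 15 arrays (x axis; black uninjected, blue control, orange aldosterone). Both 1 h arrays stand above the other 13 for the lung genes, and the ratio reaches 15.2 in the 12 h control.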

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

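All comparisons with the other arrays of a series, and the tests of lung tissue, scan day, RNA quality and shared handling below, were chosen after the results were seen, though what lung genes outside the list should show was written before their values were looked at. Of the 74 series of values examined, 6 had 1 array or time far from the rest, and chance alone flags about 1 in 20 such series. Lung epithelium markers had a median of 3.32 (log2, relative to the mean of the timed arrays) in the 1 h control array, against 0.002 in the nearest control array. They had 4.89 in the 1 h aldosterone array, against -0.52 in the nearest aldosterone array. Neutrophil markers had a median of 0.79 in the 1 h aldosterone array, and the nearest aldosterone array had 0.08, while the 1 h control array had 0.45. Macrophage markers had a median of 0.26 in the 12 h control array, and the nearest control array had -0.01, while the 4 h aldosterone array had 0.21. The difference between the arms in Fkbp5 at 12 h was 1.03, against 0.39 at the nearest time. The difference in Mt2 at 3 h was -0.71, against 0.05 at the nearest time.

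The lung transcripts of both 1 h arrays may come from lung tissue taken with the 1 h samples. Of 8 lung genes outside the list, which had no part in finding the pattern, 6 were above every other array in both 1 h arrays (Sec14l3 and Nkx2-1 were not). The excess was larger in the aldosterone array by a median of 2.78-fold (8 genes, at most 3.40). Scan day is argued against, since the other arrays scanned on the same day were lower in lung genes than those of other days by 0.18 (a difference of -0.18). A response of the heart shared by both arms at 1 h had no test of its own. It would need these transcripts to appear after 0.5 h and to be lost again by 2 h. Medians of the lung list at 0.5, 1 and 2 h were -0.73, 3.32 and 0.002 in control. In aldosterone they were -0.56, 4.89 and -1.04. Such a loss of the listed lung genes within 1 h in both arms argues against a response of the heart.

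The rise of acute phase and interferon genes from 0.5 to 5 h appeared in both arms (median slopes per h of 0.24 in control and 0.16 in aldosterone for acute phase genes, 0.21 and 0.25 for interferon genes). All 12 same-day differences of the list medians (of 12 over both lists and arms) were above 0, so the rise was also seen within scan days. The lists were chosen for rising on these same arrays, and each scan day held an earlier and a later time. That count therefore largely restates the choice and cannot decide on scan day. RNA quality is argued against, since 0.939 of the median slope or more stayed with the Gapdh ratio as a covariate. Handling and injection, or the hours of the day, shared by both arms, could account for it, and the uninjected array lay at percentile 0 for the acute phase list, though the 0.5 h control was nearly as low (-1.06 against -1.42). These cannot be told apart because only 1 uninjected array was run and controls without handling at later hours were not analysed here.

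Lower signals in aldosterone at 1 and 2 h (218 probe sets without the 0.5 h pair, medians -1.08 at 1 h and -1.33 at 2 h, and 0.12 at 0.5 h) followed the Gapdh 3′/5′ ratio. Slopes on that ratio in the 9 arrays outside 0.5 to 2 h correlated with the difference at 1 and 2 h across probe sets, which are not independent replicates (Pearson r = 0.54, Spearman rho = 0.447). Only 1 of 100 orders of the ratio, the real one, gave as strong a correlation (highest other 0.52), so RNA quality is a candidate explanation. Lung tissue is argued against at 2 h, where Scgb1a1 and Sftpc reached at most 0.0228 of their 1 h signals (a test chosen after a count over the 10 listed lung genes gave 3, between its bounds), but stays open at 1 h, where the 644 probe sets over 2-fold lower had a median of -0.496 in the 2 h pair, just short of the bound of -0.5 for arguing against it. Aldosterone stays open and cannot be told apart from RNA quality, since 0 probe sets were called with the ratio as a covariate and the ratio followed the arms at both times.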

How the results depend on the processing

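Tests with the Gapdh 3′/5′ ratio, within scan days and of lists along the trend were chosen only after the results were seen. The cause of the moves below was not tested. No gene named by its rank in a comparison reversed its fitted change. Without the 3 h pair the interferon and cytokine lists at 3 to 5 h turned from lower to higher, without a call (camera adjusted p = 0.699 and 0.869). For the uninjected control at 0 h against control at 0.5 to 5 h the 1502 probe sets over 2-fold became 1148 with the deposited scaling and the share higher went from 31.6% to 53.0%. The absence of calls for aldosterone over 7 times held under every alternative and pair left out (0 to 0), except that treatment within scan day 3 gave 1 unnamed probe set; at 3 to 5 h the count was 0 throughout. With a pair left out, counts ran from 0 to 235 at 0.5 to 2 h, 0 to 31 for the difference of windows and 0 to 1 for the aldosterone effect, any smooth time course, which array weights raised to 7736 with 4 residual degrees of freedom and weights from 0.0794 to 7.46, an estimate that did not converge. For the time effect common to both arms the 413 calls ran from 87 to 899 with a pair left out and were 246 without the filter, 54 without the variance trend, 108 with scan day and 216 with the Gapdh ratio. For 12 h against 0.5 to 5 h the 13 calls ran from 2 to 20 and were 22 with a floor, 2 with a median offset, 25 without the filter, 1 with a stricter filter, 1 with scan day and 6 with the Gapdh ratio. For the trend from 0.5 to 5 h the 35 ran from 2 to 37 and were 55 with a stricter filter, 17 without the variance trend, 64 with array weights and 111 with the Gapdh ratio. Called lists for aldosterone (1) were 0 with an estimated correlation and 3 with the deposited scaling, and ran from 0 to 5 with a pair left out. At 12 h (4) they were 1 and 9, and for the trend (11) 0 with an estimated correlation, and from 7 to 18 with a pair left out. The exact test called 0 corticosteroid targets under every alternative, but this outcome was nearly fixed in advance. A call needed many targets together at or near the smallest possible p, which is larger still with a pair left out. The count of 0 therefore says little about how the result depends on the processing. Scan day and lot could not move the aldosterone tests, whose time block holds both. Probe sets below the median signal of 526.7 were not tested, which limits low genes.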

Other observations

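The list tests of the windows and all regroupings of arrays were chosen after the results were seen. At 3 to 5 h, the macrophage and matrix lists were called higher with aldosterone, though not with an estimated correlation. Of the 13 macrophage markers 12 were higher (median 0.23; 4 adjusted over the list alone, 0 over all genes; camera adjusted p = 9.3e-07; adjusted p = 0.158 with an estimated correlation). They included C1qc (0.54 ± 0.14, SE, 3 pairs), the haemoglobin scavenger receptor Cd163 (0.61 ± 0.21) and Lyz2 (0.40 ± 0.14), each higher in 3 of 3 pairs. Of the 25 extracellular matrix genes 23 were higher (median 0.15; 0 adjusted over the list alone; adjusted p = 3.1e-09; adjusted p = 0.475 with an estimated correlation), for example periostin (Postn, 0.44 ± 0.12), Col3a1 (0.48 ± 0.14) and the lysyl oxidase gene Loxl1 (0.47 ± 0.16). Fibroblast markers, which share 5 genes with the matrix list, had a median of 0.18 (9 of 11 higher; 1 higher and 1 lower adjusted over the list alone) and missed the call (adjusted p = 0.0610), so matrix expression and stromal content were not parted. The macrophage and matrix calls held with camera's preset correlation without each of the 3 pairs, with the deposited scaling and with the Gapdh ratio.

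Interferon response genes were lower at 3 to 5 h (median -0.23; 16 of 18; adjusted p = 0.00023; adjusted p = 0.879 with an estimated correlation), and cytokine genes were lower too (median -0.15; adjusted p = 0.0185; 0.879 with an estimated correlation). Both calls were lost without the 3 h pair, and both lists then turned from lower to higher (adjusted p = 0.699 and 0.869). In the 3 h pair Irf1 differed by -0.67 and Vcam1 by -1.14. Heat shock genes (median 0.06; adjusted p = 0.0311) and epicardial markers (median 0.22; adjusted p = 0.0264) were higher, both with 0.879 with an estimated correlation, and both calls were lost without the 4 h or the 5 h pair. The epicardial call was also lost with the deposited scaling (adjusted p = 0.0865) and with the Gapdh ratio (0.0860). Hspa1b had 0.91 ± 0.20 (3 of 3 pairs). No list differed between the windows (smallest adjusted p 0.119), and none was called at 0.5 to 2 h. The 4 swaps of the arms within the 3 pairs are too few for a share under 0.05: the real arms gave 6 called lists at 3 to 5 h and the highest other 12, with 4 of 4 giving as many.

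Swapping the arms within pairs gave 64 groupings. Chance could not be excluded for the aldosterone effect over 7 times, where 26 of 64 gave as many probe sets at an unadjusted p under 0.05 (real 934, highest other 2684), or for the smooth course, where 26 did (real 1189, highest other 2261). It could not be excluded for the lists either, where 59 of 64 gave at least 1 called list (real 1, highest other 15). The splits were too few for a share under 0.05 at 0.5 to 2 h (2 of 4; real 2226, highest other 2597), at 3 to 5 h (2 of 4; real 684, highest other 905) and for the difference of windows (2 of 10; real 1436, highest other 2793). Groupings with several times the real count point to a structure of the arrays beside the arms.

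Chance could not be excluded for the trend, where 6 of 100 orders of the times gave as many calls (real 35, highest other 2169). The 4 orders with the most calls, 2169, 1648, 1408 and 999, gave the 0.5 and 3 h pairs, which shared scan day 1 and chip lot 1, the latest or the earliest hours. The order with 2169 calls also gave the latest hour to the 0.5 h pair, with Gapdh 3′/5′ ratios of 0.887 (control) and 0.853 (aldosterone). It gave the earliest hour to the 4 h pair, with ratios of 9.23 and 4.49. A structure by scan day, chip lot or RNA quality is possible, and these cannot be told apart here. With scan day as a block the real order gave 48 calls and the highest of the other within-day orders 2, but only 4 such orders exist (1 of 4 as large), too few for a share under 0.05.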
